A study of Homo sapiens with 6 samples.

How the data were processed

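RNA was sequenced from 6 samples of cells that the labels call RKO, a human colorectal carcinoma cell line, with 3 libraries in a group named Control and 3 in a group named ENZ. The series design describes the ENZ group as cells treated with a compound (A3) that degrades the histone demethylase LSD1, collected after 48 h, and calls the 3 libraries of each group biological replicates. What separated the replicates (dish, passage or day) is not given in the sources used here, so the p-values measure the spread between these libraries. What the name ENZ stands for is not given in the sources used here either. Group and replicate number were taken from the sample titles.

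Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, primed with random hexamers and made into libraries with a NEBNext Ultra kit, which keeps no record of the strand. Per the series design, the paired-end reads were 150 bp long. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.6.1 and DESeq2 1.20.0 and the GRCh38 (hg38) build. The annotation release, the strand setting and any filter are not given in the sources used here. Because the kit does not mark strand, a gene and an overlapping antisense gene cannot be told apart by their reads, and the counts of overlapping genes are uncertain.

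The authors deposited raw counts per gene and a table of FPKM values (fragments scaled to gene length and to the library total) for the same 37923 genes. The deposited FPKM values equalled the count divided by 1 length per gene and by the library's total in the count table, to within 4.69e-06 percent among values of at least 10 counts, so the FPKM table holds no measurement that the counts do not. Of the 37923 genes, 1330 had 0 counts in all libraries. No symbol was given for 9849 genes, which held 0.875% of the counts. Positions and gene types were taken from GENCODE release 44 (GRCh38), in which 37817 of the gene identifiers were found. Symbols were used as the files give them.

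Library totals ran from 26691289 to 30025543 counts. Within a group, pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 1.99 and 6.77, which separate preparations from 1 sample could also give. Each library was counted as a replicate because the series design calls it one. A count of 0 in a library allows a level of up to 3 counts, which was 0.100 to 0.112 CPM, for counting error alone. CPM values are counts scaled to a library total of 1000000 and are given as mean ± SD over the 3 libraries of a group.

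The groups were compared with edgeR 4.0.16 (R 4.3.3), using TMM factors, the default expression filter, robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 18581 genes kept. Fold changes are log2 of ENZ over Control. The standard error (SE) is the absolute log2 fold change divided by the square root of F. A gene was called at an adjusted p under 0.05, and calls with an absolute log2 fold change over 1 were counted separately because the series design states that limit. All adjusted p-values of genes are from this test unless another is named.

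Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 34 lists that were fixed before the data were examined. Camera with an estimated correlation and fry's directional test were run beside it. Another 4 lists (prostate luminal lineage, androgen response, glucocorticoid response, and genes of RKO and other colorectal lines) were written after the gene tests had been seen. Their p-values are adjusted over these 4 lists, and those with an estimated correlation also over all 38.

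Named genes followed a rule fixed before the data were examined: 10 genes of the study's subject (KDM1A, GPX4, SLC7A11, ACSL4, AIFM2, TFRC, FTH1, NFE2L2, HMOX1 and CDKN1A); the 10 largest fold changes in each direction among called genes with an absolute log2 fold change over 1, a mean of at least 1 CPM and groups that did not overlap, pseudogenes and unnamed clones left out; the 5 smallest p-values in each direction among the same genes; and up to 3 called members with the smallest p in each list, or the tested member with the smallest p where none was called. Other genes, named where a count or a list is explained, were chosen after their values were seen.

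The alternatives were DESeq2 1.42.0, limma-voom, median-ratio size factors, library totals alone, no filter on low counts, a filter of at least 10 counts in 3 libraries, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean of at least 1 FPKM, limma on unfiltered log2(FPKM + 1), and each library left out in turn. Offsets per library fitted to GC content and length with natural splines (4 degrees of freedom each) were added after fold changes had been seen to rise with GC content. GC content was that of the longest GENCODE transcript, known for 99.8% of tested genes, and length was that implied by the deposited values.

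The gene test was tested on simulated data: negative binomial counts for 18581 genes with the means, library sizes and dispersions of these libraries, of which 200 were changed by known folds. It recovered 28 of 50 genes changed 1.25-fold, 33 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 48 of 50 changed 4-fold, and 7.2% of its calls were false. With no gene changed it called 0 genes. A set of 40 genes raised 1.25-fold had a camera p of 5.43e-35, and an unchanged set of the same size 0.58. The simulated genes varied independently of one another, so these sets do not show how camera performs on lists of correlated genes. In the data the estimated inter-gene correlation reached 0.664, for the ribosomal protein list.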

Results

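The transcriptomes of 6 samples of cells labelled RKO were compared, 3 in the Control group and 3 in the ENZ group, which the series design describes as exposed to a degrader of LSD1 for 48 h. Libraries held 26691289 to 28207612 counts in the Control group and 26756840 to 30025543 in the ENZ group. Log2 CPM correlated at 0.994 to 0.995 between libraries of a group and at 0.985 to 0.989 between groups, and the first principal component, with 56.0% of the variance, separated the groups.

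The question was which transcripts differ between the libraries labelled ENZ and Control. Only the series design links ENZ to the LSD1 degrader, and whether these libraries had that exposure was not tested, so the differences below are those between the 2 labels. In the libraries labelled ENZ, BMF, a pro-apoptotic member of the BCL2 family, rose 5.02-fold (30.4 ± 0.572 CPM in Control and 149 ± 1.64 in ENZ, SD, n = 3; log2 fold change 2.33 ± 0.05 SE; adjusted p = 4.38e-20 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). FKBP5, a co-chaperone of steroid hormone receptors, fell from 1053 ± 22.8 to 344 ± 3.88 CPM, a log2 fold change of −1.58 ± 0.03 (adjusted p = 8.99e-20). MBOAT2, a phospholipid acyltransferase known to restrain ferroptosis, fell by 2.36 on the log2 scale, from 114 ± 5.68 to 21.7 ± 1.74 CPM (adjusted p = 1.55e-18). In GRCh38 BMF (ENSG00000104081) lies on chromosome 15 from 40087890 to 40108892, FKBP5 (ENSG00000096060) on chromosome 6 from 35573585 to 35728583 and MBOAT2 (ENSG00000143797) on chromosome 2 from 8852690 to 9003709. The aryl hydrocarbon receptor target CYP1A1 rose 2.97-fold, to 132 ± 0.308 CPM, and the lipogenic transcription factor SREBF1 rose 2.48-fold, to 307 ± 8.89 CPM.

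In all, 7393 of 18581 tested genes were called, 3814 higher and 3579 lower in ENZ. Which direction had more calls differed between settings, with 3097 higher and 4104 lower on library totals alone and 2526 and 2871 on log2(FPKM + 1) values. An absolute log2 fold change over 1 was reached by 553 of them, 137 higher and 416 lower. Most calls were small, with 5314 under an absolute log2 fold change of 0.5. The largest rises under the naming rule, after BMF, were in the matrix protein gene MATN2 (log2 fold change 2.11 ± 0.09), in BAMBI, a pseudoreceptor that dampens TGF-beta signalling (1.86 ± 0.07), and in FREM3, PDE7B, EFHD1, LDLRAD4, DLX3, PCED1B and GSTA3, which rose 2.98-fold to 3.55-fold. Small p-values among rises were also found for GALNT10 (2.39-fold) and the epithelial transcription factor ELF3 (2.03-fold). The largest falls under the same rule, which asks for a mean of at least 1 CPM, were in THSD7A (log2 fold change −3.60 ± 0.14, from 15.9 to 1.28 CPM), in the amino acid transporter SLC38A4 (−3.22 ± 0.10, from 21.6 to 2.27 CPM) and in ATOH1, a transcription factor of secretory cells (−3.12 ± 0.28, from 2.11 to 0.231 CPM). GMNC, the phosphodiesterase PDE3A, DCN, the deiodinase DIO2 and DLX5 fell, with log2 fold changes from −2.89 to −2.51. CHRNA2 fell by 2.48, the scaffold protein gene AKAP12 by 1.83 and DOCK8 by 1.58. POTEH-AS1 (−2.71) and DOCK8-AS2 (−2.64) also fell, but both are antisense genes, DOCK8-AS2 overlaps DOCK8 (chromosome 9, 452492 to 492248, against 214854 to 465259, GRCh38), and reads of the strands were not separable.

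**Figure D1:**
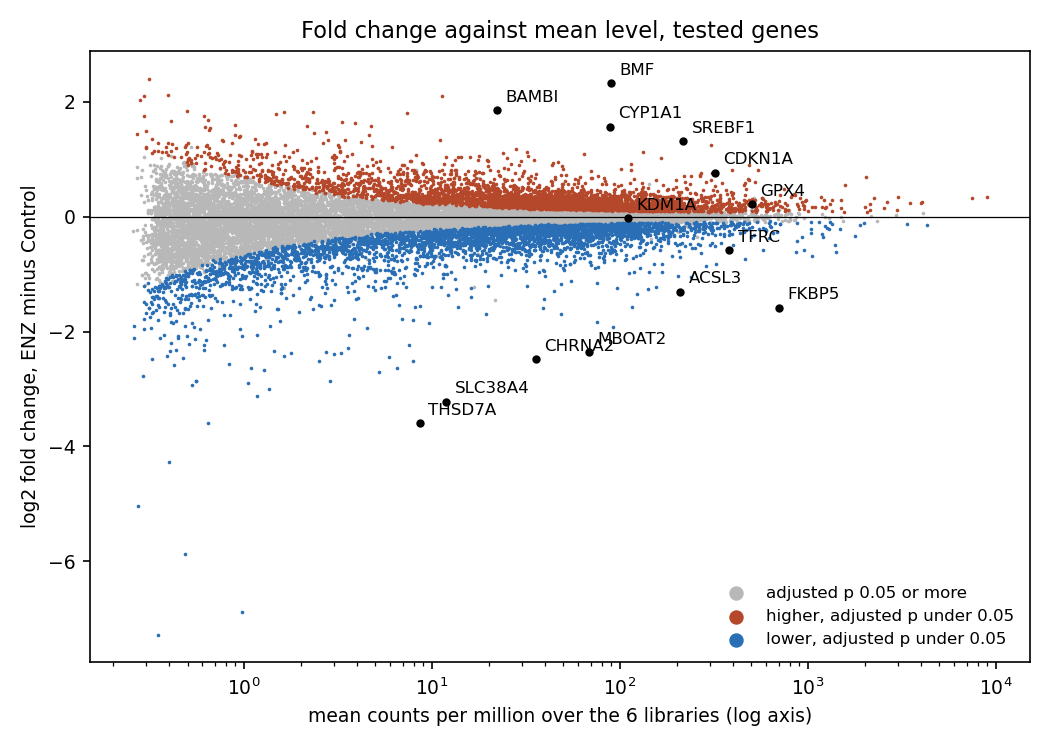
Log2 fold change (ENZ minus Control) of each of the 18581 tested genes against its mean CPM on a log axis; red and blue points are the 3814 higher and 3579 lower calls. BMF lies highest among the labelled genes at 2.33 and THSD7A lowest at −3.60, while KDM1A lies at −0.02.

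KDM1A, the gene that encodes LSD1 (chromosome 1, 23019443 to 23083689, GRCh38), had 113 ± 2.15 CPM in Control and 108 ± 3.18 in ENZ, a log2 fold change of −0.02 (95% confidence interval −0.11 to 0.06; adjusted p = 0.681). A degrader acts on the protein, so the transcript is no check of the exposure. Among 18 tested genes of the LSD1-CoREST complex and its partners, 8 rose and 0 fell (8 and 0 adjusted over the list alone), ZNF217 by 0.38, HDAC1 by 0.22 and GFI1 by 0.50 on the log2 scale; camera did not call the list (adjusted p = 0.111). Histone methylation enzymes went both ways, with 15 rising and 7 falling of 43 (16 and 9 adjusted over the list alone; camera adjusted p = 0.111). In that list the demethylase genes KDM5B and KDM6B rose by 0.58 and 0.36, and PHF8 fell by 0.40.

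Genes that restrain ferroptosis, an iron-dependent death by lipid peroxidation, did not move together. Of 32 tested suppressors 8 rose and 8 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.719), with a median log2 fold change of 0.06 and a mean of −0.04. GPX4, the peroxidase that reduces lipid hydroperoxides, rose by 0.22 ± 0.04, from 470 to 532 CPM (adjusted p = 3.04e-04). The cystine transporter SLC7A11 had 210 ± 11.9 CPM in Control and 181 ± 23.1 in ENZ (log2 fold change −0.18, interval −0.39 to 0.02; adjusted p = 0.145). Without ENZ replicate 1 its log2 fold change was −0.28 with a call, and with GC and length offsets it was 0.05. ACSL3, which activates monounsaturated fatty acids, fell by 1.31 ± 0.05, and the desaturase SCD rose by 0.81 ± 0.03. AIFM2 had a log2 fold change of 0.06 (adjusted p = 0.839) and NFE2L2 of 0.11 (adjusted p = 0.145). Among 33 ferroptosis drivers and markers, 7 rose and 9 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.719). TFRC, the transferrin receptor, fell by 0.58 ± 0.03 (463 to 302 CPM), TMEM164 by 0.78 and the elongase ELOVL5 by 0.49, HMOX1 rose by 0.43 ± 0.08, and ACSL4 had a log2 fold change of −0.07 (adjusted p = 0.498). With GC and length offsets ACSL4 turned to a called rise of 0.16 (adjusted p = 0.0435). Of 27 iron-handling genes 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.508), the zinc and iron transporter SLC39A8 by 0.96 and STEAP2 by 1.03 downwards. The ferritin heavy chain FTH1 had an adjusted p of 0.0441 at a log2 fold change of 0.21, and that call ended in 9 of the 17 settings tried.

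Stress-related lists differed in direction. Of 38 tested ATF4 targets, the genes of the integrated stress response, 28 rose and 0 fell (32 and 0 adjusted over the list alone), with GDF15 up by 0.90, DDIT4 by 0.92 and PCK2 by 0.81 on the log2 scale. Camera called the list (adjusted p = 6.65e-10), and the call was lost with an estimated correlation (adjusted p = 0.451 with an estimated correlation). Of 24 genes of the unfolded protein response, 2 rose and 20 fell (2 and 20 adjusted over the list alone), among them the endoplasmic reticulum chaperones PDIA4 (−0.73), HYOU1 (−0.58) and HSPA5 (−0.49; 1648 to 1142 CPM). Its camera adjusted p was 1.18e-06 (adjusted p = 0.451 with an estimated correlation). NRF2 targets had 14 rises and 5 falls among 29 (15 and 5 adjusted over the list alone), with NQO1 up by 0.62, TKT up by 0.55 and the efflux transporter ABCC4 down by 0.92; camera's adjusted p was 0.0247 (adjusted p = 0.451 with an estimated correlation), and the call also ended on log2(FPKM + 1) values (adjusted p = 0.18). Heat shock genes divided, 8 rising and 10 falling of 21 (8 and 10 adjusted over the list alone; camera adjusted p = 0.719), HSP90AA1 by 0.62 and HSPH1 by 0.58 downwards and HSPA1B by 0.35 upwards; HSPA1B has a near-identical copy, HSPA1A, and its count is uncertain. Of 34 p53 targets 11 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0995), including the cell cycle inhibitor CDKN1A, which rose by 0.77 ± 0.04 from 240 to 400.0 CPM, and TP53INP1, which rose by 0.73.

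Of 40 tested G2/M and mitosis genes 32 fell and 1 rose (32 and 1 adjusted over the list alone), with a median log2 fold change of −0.33; CDK1 fell by 0.51, KIF23 by 0.42 and MKI67 by 0.35. Camera's adjusted p was 2.81e-09 (adjusted p = 0.42 with an estimated correlation). Of 42 DNA replication and G1/S genes 22 fell and 3 rose (23 and 3 adjusted over the list alone), RRM2 by 0.34 and CLSPN by 0.41 downwards; camera's adjusted p was 0.00204 (adjusted p = 0.451 with an estimated correlation). MYC and ribosome biogenesis genes had 10 falls and 4 rises among 38 (10 and 4 adjusted over the list alone; camera adjusted p = 0.519), with ODC1, NCL and DDX18 down by 0.22 to 0.31. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 2 rises among 20 (2 adjusted over the list alone; camera adjusted p = 0.719).

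Of 67 cytosolic ribosomal protein genes 57 rose and 0 fell (61 and 0 adjusted over the list alone), with a median log2 fold change of 0.21, RPL4 by 0.34, RPL13A by 0.30 and RPL15 by 0.29; their pseudogenes make single counts uncertain. Camera's adjusted p was 1.69e-10 (adjusted p = 0.508 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 24 rises and 1 fall among 48 (28 and 1 adjusted over the list alone), with UQCRFS1, UQCRC2 and SDHC up by 0.25 to 0.29 and a camera adjusted p of 2.55e-04 (adjusted p = 0.508 with an estimated correlation). Of 13 mitochondrially encoded genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.342), MT-ND2 by 0.70, MT-ND1 by 0.55 and MT-CO1 by 0.33 upwards and MT-ND4 by 0.13 and MT-ND4L by 0.21 downwards. Autophagy and lysosome genes had 19 rises and 3 falls among 40 (20 and 3 adjusted over the list alone), NEU1 by 0.43, GABARAPL2 by 0.37 and SESN2 by 0.42 upwards, with a camera adjusted p of 9.11e-04 (adjusted p = 0.451 with an estimated correlation). Proteasome and degrader machinery genes had 15 rises and 5 falls among 44 (18 and 5 adjusted over the list alone; camera adjusted p = 0.0995), NFE2L1 by 0.38 and VHL by 0.28 upwards.

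**Figure D2:**
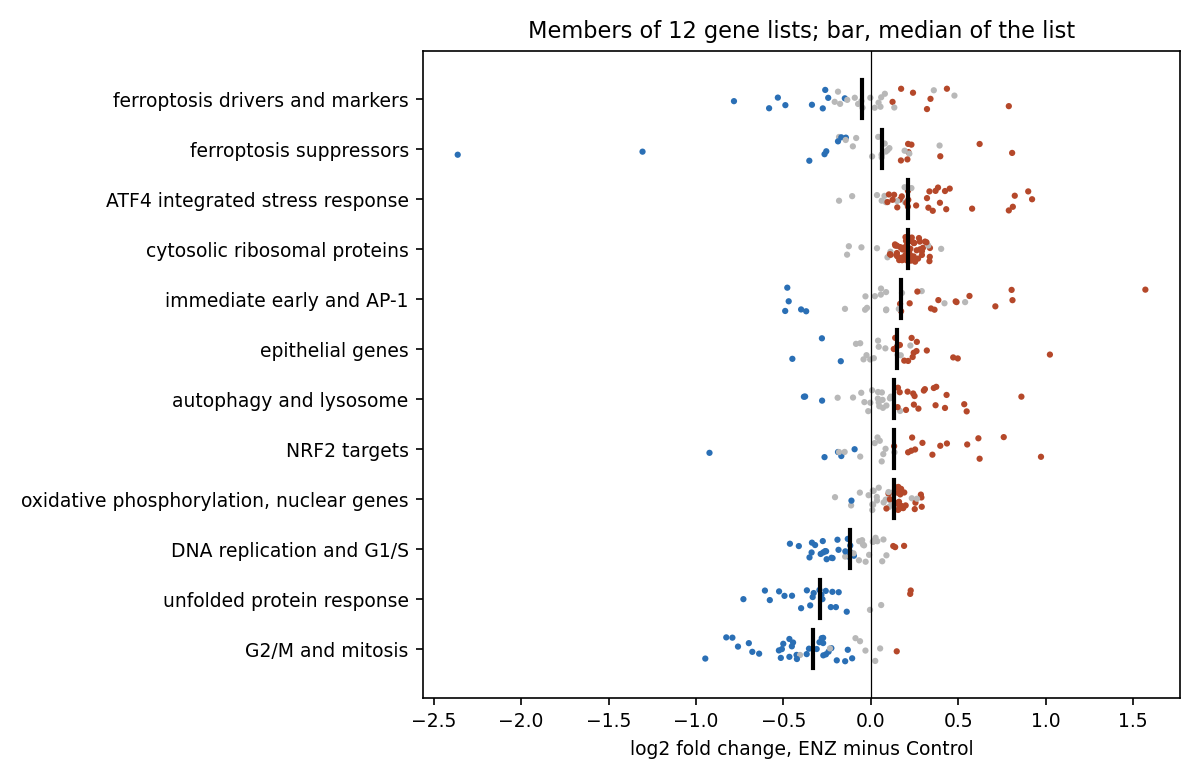
Log2 fold change (ENZ minus Control) of each tested member of the 10 lists called by camera with the preset correlation and of the 2 ferroptosis lists; red points rose, blue points fell, grey points were not called, and the bar is the median of the list. The medians run from −0.33 for G2/M and mitosis to 0.21 for ATF4 targets and ribosomal proteins, and none of the 10 calls held with an estimated correlation.

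Lipid genes also moved in both directions. Of 23 genes of fatty acid synthesis and activation 8 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.262), with SREBF1 and SCD rising and ACSL3 falling as above. Among 24 cholesterol synthesis genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0995), TM7SF2 by 0.62, FDFT1 by 0.32 and SREBF2 by 0.30 upwards.

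Epithelial genes had 15 rises and 3 falls among 30 (15 and 3 adjusted over the list alone), ELF3 by 1.02, CLDN7 by 0.47 and CLDN3 by 0.50 upwards. Camera's adjusted p was 0.0153 (adjusted p = 0.451 with an estimated correlation), and the call ended with GC and length offsets (adjusted p = 0.139). Of 21 mesenchymal genes 6 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.986), with FN1 down by 1.30, LOX down by 1.55 and CDH2 up by 1.24; the median was 0.11 and the mean −0.12. Immediate early and AP-1 genes had 14 rises and 5 falls among 34 (16 and 5 adjusted over the list alone), with JUNB up by 0.71, JUND by 0.48 and EGR1 by 0.81 and a camera adjusted p of 0.00933 (adjusted p = 0.451 with an estimated correlation). Of 35 hypoxia and glycolysis genes 7 rose and 13 fell (7 and 13 adjusted over the list alone; camera adjusted p = 0.519), DDIT4 rising and LOX and P4HA1 (−0.51) falling; the median was 0.01 and the mean −0.16.

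Immune-related lists showed few common changes. Interferon-stimulated genes had 6 rises and 6 falls among 30 (6 and 6 adjusted over the list alone; camera adjusted p = 0.993), with HERC5 down by 1.22, PARP14 down by 0.49 and MX1 up by 0.78. Antigen presentation genes had 8 rises and 2 falls among 16 (8 and 4 adjusted over the list alone; camera adjusted p = 0.111), NLRC5 by 1.08, HLA-B by 0.41 and HLA-C by 0.26 upwards; HLA genes share reads with one another. NF-kB and cytokine genes had 4 rises and 3 falls among 12 (4 and 3 adjusted over the list alone; camera adjusted p = 0.986), with TNFAIP3 down by 1.60, BIRC3 down by 1.33 and NFKBIA down by 0.19; the median was 0.02 and the mean −0.09.

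Of 25 enterocyte differentiation genes in the table, 18 had a mean under 1 CPM and 2 were over 10 CPM; among the 8 tested 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.519), VIL1 upwards by 0.57 and SLC26A3 and HNF4G downwards by 2.06 and 0.52. CDX1 and KRT20 did not exceed 0.04 CPM in any library and HNF4A did not exceed 0.20 CPM. Secretory and enteroendocrine genes had 3 rises and 4 falls among 21 tested (3 and 4 adjusted over the list alone; camera adjusted p = 0.719), with AGR2 down by 0.69, ATOH1 down as above and ENO2 up by 0.35. WNT and intestinal stem cell genes had 7 rises and 3 falls among 21 (7 and 3 adjusted over the list alone; camera adjusted p = 0.111), CCND1 by 0.26 and DKK1 by 0.50 upwards and LGR4 by 0.60 downwards. Markers of leukocytes, fibroblasts and endothelium were mostly low, with 16 of 18, 9 of 16 and 12 of 13 under 1 CPM. In these lists the called genes were CORO1A (−0.44), LUM (−1.18), DCN (−2.66), TWIST1 (0.18) and ENG (−0.67), counts that were equal when adjusted over the list alone, and camera's adjusted p was 0.719 for each list.

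Genes typical of prostate luminal cells were abundant in all 6 libraries labelled RKO. The list that measures this was written after the gene tests had been seen, when SLC45A3, STEAP1 and STEAP2 were already known to change, and it shares 7 genes with the androgen response list. FOLH1, which encodes prostate-specific membrane antigen, had 626 ± 3.69 CPM in Control and 857 ± 5.71 in ENZ. HOXB13 had 157 ± 2.65 and 193 ± 4.16 CPM, and KLK4 had 153 ± 2.62 and 113 ± 2.37. KLK3 was low, at 4.91 ± 0.880 and 3.82 ± 0.611 CPM. Of 23 genes of the list in the table, 12 had a mean over 10 CPM and 5 were under 1 CPM. GSTP1, which many colorectal lines express, did not exceed 0.07 CPM in any library.

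**Figure D3:**
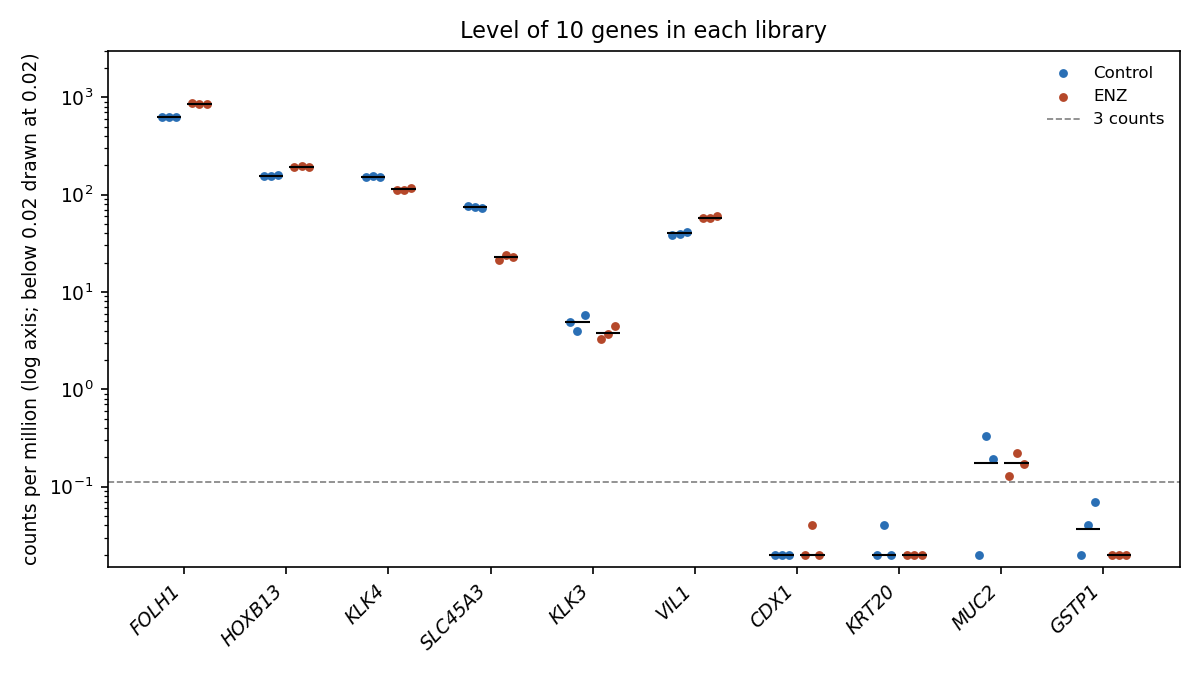
CPM of 10 genes in each of the 6 libraries on a log axis, Control in blue and ENZ in red, with the group mean as a black bar; values below 0.02, including 0, are drawn at 0.02, and the dashed line is the level of 3 counts. FOLH1 and HOXB13 lie above 100 CPM in every library, and CDX1, KRT20 and GSTP1 below the line.

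Among 19 tested prostate luminal genes 6 rose and 9 fell (camera adjusted p = 0.236 over the 4 added lists), with SLC45A3 down by 1.69 ± 0.06, STEAP1 by 1.22 ± 0.04 and STEAP2 by 1.03 ± 0.05, and TMPRSS2 up by 0.75 and FOLH1 by 0.49. Of 95 androgen response genes 46 fell and 19 rose, with a median log2 fold change of −0.15; FKBP5 fell by 1.58, AKAP12 by 1.83 and the prostaglandin dehydrogenase HPGD by 1.92. Camera's adjusted p for this list was 3.8e-04 over the 4 added lists. With an estimated correlation it was 0.0262 over the 4 lists and 0.235 over all 38, so that call depended on the family adjusted over (adjusted p = 0.235 with an estimated correlation). Of 19 glucocorticoid response genes 13 fell and 2 rose, with a median of −0.37; ZBTB16 fell by 0.89, PER1 by 0.88 and SGK1 by 1.40, while TSC22D3, a classical target of the glucocorticoid receptor, rose by 0.94. Its camera adjusted p was 4.72e-06 over the 4 lists (adjusted p = 0.0491 with an estimated correlation over the 4 lists and 0.311 over all 38). Androgen and glucocorticoid lists share 2 genes. Genes of RKO and other colorectal lines had 1 rise and 1 fall among 6, S100A6 by 0.28 upwards and CD44 by 0.40 downwards (camera adjusted p = 0.969).

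Fold changes rose with the GC content of the transcript, which bears on every list above. The median log2 fold change was −0.18 in genes under 40% GC and 0.14 in genes over 60% GC, and Spearman's rho across tested genes was 0.34 (genes are not independent replicates). With offsets per library for GC content and length, chosen after this was seen, 7702 genes were called, 5711 of them among the 7393, and 514 passed the fold limit. The G2/M and mitosis list kept a median of −0.32 and the ATF4 list one of 0.22. The epithelial call ended, and 3 lists not called as tested were called with the offsets, p53 targets (camera adjusted p = 0.0429), cholesterol synthesis (0.0486) and proteasome and degrader machinery (0.0153); without the offsets their adjusted p-values with an estimated correlation were 0.451, 0.451 and 0.725. Of the tested genes 9151 (49.2%) had groups that did not overlap in CPM. Chance gives 10% for a single gene at 3 against 3, but genes shift together with a library. The share over all genes can therefore lie far from 10% without a group effect. CPM here uses library totals without the TMM factors, which were 1.008 to 1.016 in Control and 0.982 to 0.995 in ENZ. DESeq2 called 5868 genes, of which 364 passed the fold limit, against 553 in edgeR.

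**Figure D4:**
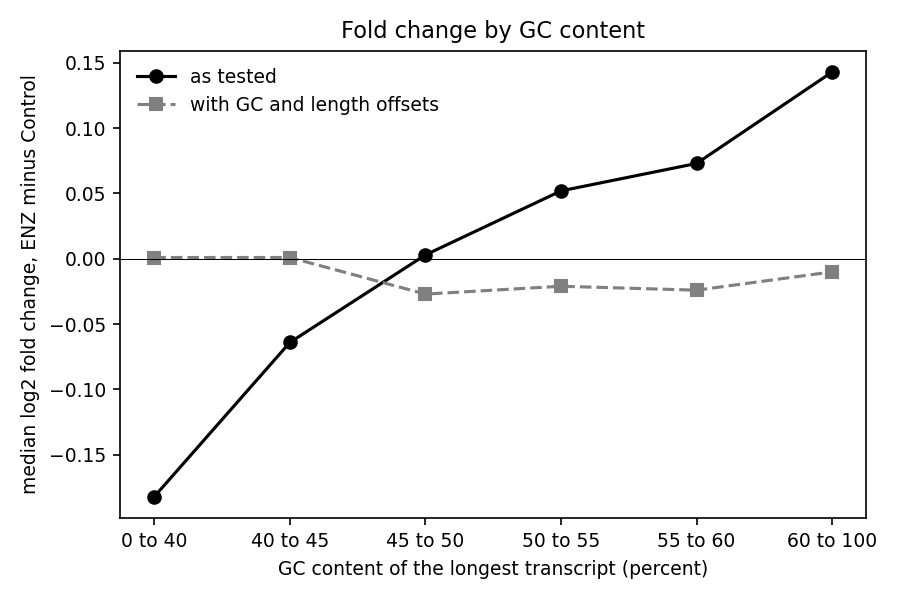
Median log2 fold change (ENZ minus Control) of tested genes in 6 bins of GC content in percent, as tested (circles) and with offsets per library for GC content and length (squares). The median rises from −0.18 in the lowest bin to 0.14 in the highest, and with the offsets it lies between −0.03 and 0.00.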

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

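The GC and length offsets and the 4 added lists were chosen after the data were seen, and the other settings before the data were examined. Of 130 named genes 117 kept their direction and side of the threshold in all 17 settings that gave them a value. Most named genes were chosen from these data for a small p or a large fold, and 125 were called. Their share is therefore no measure of how stable all calls were. Among the 7393 reported calls, 5823 were also called by DESeq2 and 5711 with the offsets. Over all settings the shared calls ran from 3474 on unfiltered log2(FPKM + 1) to 7387 with the filter of at least 10 counts. Among the lists that camera called, 0 changed direction. Leaving out each library gave 5844 to 8258 called genes, 503 to 690 over the fold limit and 10 to 11 called lists. Calls over the fold limit, 553 as reported, were 364 in DESeq2, 62 on log2(FPKM + 1), 147 on log2(FPKM + 0.1) and 60 on unfiltered log2(FPKM + 1), where 3728 genes were called in all; a pseudocount shrinks the folds of low genes by construction, and for DESeq2 the cause was not tested. The 10 called lists became 0 with an estimated correlation, 24 with fry, which tests no contrast with other genes, and 17 without a filter. A call lost with an estimated correlation need not reflect correlation between genes. The androgen response list had an estimated correlation of −0.004, below the preset 0.01. Camera's unadjusted p for that list still rose, from 1.9e-04 to 0.00655. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.018, −0.012 and −0.046), and the fit with a replicate block called 7466 genes, 532 of them over the fold limit, and 10 lists; with the replicate block SLC7A11 was called at −0.19, the only one of the 130 genes whose call it changed. SLC7A11 was also called without the filter (−0.18), ranged from −0.28 to −0.10 with libraries left out, with a call without ENZ replicate 1, and turned to 0.053 with the offsets. GPX4 lost its call on unfiltered log2(FPKM + 1) (0.18). With libraries left out KDM1A ranged from −0.048 to 0.005, ACSL4 from −0.16 to 0.02 and AIFM2 from −0.033 to 0.22, and the offsets gave 0.16 for ACSL4, with a call, and −0.031 for AIFM2, without one. Medians of some lists that camera did not call changed sign, and the cause was not tested. With the offsets these were ferroptosis drivers (0.042), heat shock (0.000), secretory lineage (0.05), hypoxia (−0.037), fibroblast markers (−0.02) and colorectal line genes (−0.018). On log2(FPKM + 1) they were interferon-stimulated genes (0.015), NF-kB (−0.097), enterocyte genes (0.015), secretory lineage (0.093), hypoxia (−0.025) and histones (0.034). On library totals alone they were NF-kB (−0.013), hypoxia (−0.024) and colorectal line genes (−0.016), and without a filter NF-kB (−0.027), hypoxia (−0.004) and fibroblast markers (−0.31). With libraries left out, medians ranged from −0.052 to 0.063 for interferon-stimulated genes, −0.014 to 0.073 for NF-kB and −0.265 to 0.045 for enterocyte genes. They ranged from −0.01 to 0.007 for hypoxia, −0.118 to 0.065 for histones and −0.034 to 0.021 for MYC and ribosome biogenesis genes. For leukocyte markers the range was −0.148 to 0.009, and for colorectal line genes −0.024 to 0.026. Simulated 1.5-fold changes were recovered for 66% of genes and 2-fold changes for 92%. That simulation changed only 200 of 18581 genes, against 7393 called here, so its adjusted threshold was stricter. Its shares therefore do not measure how complete the calls reported here are.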

Other observations

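The tests of GC content, of the marker levels and of the added lists were chosen after the gene tests had been seen, and the bounds that decide them were written before their own values were, except that the bootstrap intervals were added once the medians had been seen and that the test of non-coding and unspliced transcripts was narrowed to non-coding ones once its value had been seen. Long non-coding RNA genes leaned downwards in the libraries labelled ENZ. Of 3042 tested, 120 rose and 560 fell, with a median log2 fold change of −0.18, while the 13724 protein-coding genes had a median of 0.03.

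The 6 libraries labelled RKO held FOLH1 and HOXB13 above 100 CPM in every library. A candidate explanation is that they came from cells other than RKO, which is not decided here. RNA of other cells mixed into RKO libraries would need strong VIM, CAV1, GSTP1 and LGALS1, whose median was 9.64 CPM in the lowest library, between the bounds of 5 and 50 set for that test, with LGALS1 near 102 CPM and GSTP1 at 0.07 CPM or less. Both stay open because no RKO library was analysed here for comparison, and no biological explanation was tested.

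Androgen response genes and mitotic genes were lower in the libraries labelled ENZ, and both lists are poor in GC, at 43.4% and 42.2% against 48.0% for tested genes. For the mitotic list a GC bias of the libraries is argued against as the whole cause, since with GC and length offsets the median was −0.319 (bootstrap interval −0.358 to −0.259), beyond the bound of −0.2. The androgen list had a median of −0.103 with the offsets (interval −0.212 to −0.024), which spans the bound of −0.1, so a GC bias stays open for it. Whether the exposure lowered the androgen response genes by way of hormone signalling was not tested. In that list 46 genes fell and 19 rose. In the glucocorticoid response list 13 fell and 2 rose, with FKBP5 and SGK1 falling and TSC22D3 rising, and the prostate luminal gene TMPRSS2 rose. In the mitotic list 32 fell and 1 rose.

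The rise of fold changes with GC content was also examined. Fewer non-coding transcripts in the libraries labelled ENZ would leave little trend within protein-coding genes, where Spearman's rho was 0.40, which argues against this as the whole cause; for unspliced transcripts, which come largely from protein-coding genes, this value decides nothing. A GC bias that varies from library to library would make the libraries' GC slopes overlap between the groups. They did not overlap, but the gap between the groups was 0.37 of the widest range within a group (0.037 against 0.101 log2 units per 10 points of GC), too small to exclude it. A technical and a biological source of the trend cannot be told apart here, because all 3 ENZ slopes lie above all 3 Control slopes.

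With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one had libraries of both labels on each side, so the difference between the labels added to its spread. Low counts in those splits therefore do not show what chance alone gives. The real split called 7393 genes, 553 of them over the fold limit, and the highest count among the other splits was 0 for both. At an unadjusted p under 0.05, edgeR gave 8883 genes for the real split and at most 988 for another split. In each case 1 of the 10 splits, the real one, gave as many genes.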
